A study of Macaca mulatta with 6 samples.

How the data were processed

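Small RNA was sequenced from whole testis of 6 juvenile wild-type rhesus monkeys, 3 given vehicle and 3 given pulses of follicle-stimulating and luteinizing hormone for 48 h. The titles and the design text name the Ion Torrent platform, whereas the extraction protocol per the labels describes a stranded total RNA kit and Illumina library steps; which of these made the small RNA libraries was not given in the sources used here. Each animal has its own number in the titles (7, 9 and 11 for vehicle; 8, 10 and 12 for gonadotropin), and libraries are called by group and number.

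The authors deposited 2 tables of raw counts. The miRNA table holds the count per mature miRNA from miRDeep2 on rheMac2, per the labels. The small RNA table holds the count per annotated small RNA gene from HTSeq on rheMac8, with Ensembl gene identifiers, per the labels. The submitters' processing notes list cutadapt 1.9.1, Bowtie 1.1.2, HTSeq 0.6.1p1 and edgeR; the versions of miRDeep2 and edgeR, the handling of reads that map to several places and the strand setting were not given in the sources used here. The authors also deposited the results of an edgeR exact test for each table, with log2 fold changes, p-values, their adjusted values and CPM. Their rows are those with more than 1 CPM in at least 3 libraries, as tested on the values. The deposited CPM columns sum to 1000000 per library, so no scaling factor between libraries is visible in them, although the headers of the miRNA table name TMM. The log2 fold changes and p-values of the authors were used only for comparison, and the counts for everything else.

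Total counts per library ran from 1100190 to 1747355 in the miRNA table and from 2146412 to 3170784 in the small RNA table. Rows with too few counts were removed with filterByExpr (minimum count 10, by group), which kept 433 of 701 mature miRNAs and 717 of 3083 small RNA genes. Counts were scaled by TMM and tested with the quasi-likelihood test of edgeR 4.0.16 (robust fit) in R 4.3.3, gonadotropin against vehicle, with Benjamini-Hochberg adjustment and a threshold of 0.05. Levels are TMM-scaled CPM, as mean ± SD over 3 libraries, and fold changes are log2 with a standard error (SE). This SE is approximate: it is the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. The biological coefficient of variation was 35.1% in the miRNA table and 46.2% in the small RNA table. With 3 libraries against 3, the smallest p of an exact permutation test is 0.1. Reads carry no molecular identifiers here, so counts are reads and not molecules.

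Of the fixed lists, 18 of miRNAs could be tested in the miRNA table, and the same kinds of lists and 11 classes of small RNA gave 29 in the small RNA table. They were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with its preset correlation of 0.01, for lists with at least 3 tested members, and again with an estimated correlation and with fry. The p-value of fry asks whether the members of a list move one way on balance, and its mixed p-value whether they change in either direction; neither compares the list with other genes. Lists of markers of blood, endothelium, muscle, duct epithelium, liver and neural cells stood for other cells that a piece of testis could hold. Lists of messenger RNAs were not tested here. The groups, tests, lists, most alternatives and the rule for naming genes were fixed before the data were examined. That rule took, per table, called genes that separate the groups, filled up to 10 per direction by smallest p, the 5 most abundant, the members of each list with the smallest p, genes past 0.05 in the authors' tables, and miRNAs near DIO3 or tied to gonadal hormones.

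Gene names in the small RNA table came from that table or, for 60 of its 554 genes without a name, from a table of gene names that held 1328 of the 3083 identifiers. Of the tested small RNA genes, 128 had counts within 5% of another gene in every library, so reads of near-identical copies may be split or counted more than once, and values of such copies are uncertain. Among mature miRNAs, 10 names had counts identical to another name (total of 30 or more), and no name was duplicated. Antisense and overlapping genes could not be told apart without the strand setting.

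The scripts were tested on simulated counts with the means and library sizes of these libraries. With 433 genes of the miRNA table, 31% of 100 genes changed 2-fold and 94% of 100 genes changed 4-fold were recovered, and 1.57% of the 127 called genes were unchanged. With 717 genes of the small RNA table, 12% and 82% were recovered for the same folds and numbers of changed genes, and 4.08% of the 98 called genes were unchanged. So many changed genes at once ease the adjusted threshold, so recovery is likely lower where few genes change. With no gene changed, 0 were called in either table. A list of 36 genes shifted by 0.5 (log2) was called in both tables, and 0 unshifted lists were. The genes of these simulated lists varied independently, whereas the members of real lists correlate, at an estimated 0.261 for DLK1-DIO3 in the miRNA table. The simulation therefore cannot show how often camera calls unchanged real lists at its preset correlation. The search for losses in a single library found 100% of 5 planted 32-fold losses in each table. These were planted in abundant genes only, so the recovery of smaller losses or of losses in scarcer genes is not known. Alternatives covered the scaling (DESeq2 size factors, upper quartile, library totals) and the filter. They covered the test (DESeq2 1.42.0, the edgeR exact test, limma voom, a fit without robust estimation). Age as a covariate or as pairs, and leaving out each library, were run too. A looser threshold of 0.10 on the main fit was counted as an alternative as well, and it repeats the p-values of the main test. Library totals alone moved the median log2 fold change of all tested rows in the miRNA table to 0.19, from -0.06 with TMM. In the small RNA table it moved to 0.09, from -0.02. The TMM factors of the miRNA table did not overlap between groups, at 0.84 to 0.97 in vehicle and 1.07 to 1.13 in gonadotropin libraries. The choice of scaling thus shifts the fold changes of that table as a whole. The factors of the small RNA table overlapped between groups. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.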

Results

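Small RNA libraries were made from the testes of 6 juvenile rhesus monkeys, 3 infused with vehicle (animals 7, 9 and 11, aged 24, 14 and 15 months) and 3 infused with pulses of follicle-stimulating hormone and luteinizing hormone for 48 h (animals 8, 10 and 12, aged 22, 14 and 15 months). The infusion imitates the hormone drive of early puberty. The series asks whether gonadotropins change testicular miRNAs at that stage and whether such miRNAs bear on the thyroid hormone state of the testis, in which the enzyme DIO3 inactivates thyroid hormone. Total counts were 1100190 to 1747355 per library over 701 mature miRNAs and 2146412 to 3170784 over 3083 small RNA genes. Vehicle 7 stood apart from the other libraries: the principal component that held 47.5% of the variance of the miRNA table placed it at -14.77, with the others between -2.54 and 6.90. In the small RNA table gonadotropin 10 stood apart on the second component (30.7% of the variance, 22.17 against -8.18 to -1.71).

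miR-503-5p was the only mature miRNA that passed the edgeR quasi-likelihood test, with higher counts in the gonadotropin libraries. Its level was 2521 ± 262 CPM in vehicle and 9207 ± 3552 CPM in gonadotropin testes (SD, n = 3 each), a log2 fold change of 1.87 (SE 0.34, adjusted p = 0.0497 by the edgeR quasi-likelihood test). miR-503 is encoded on the X chromosome (132771696 to 132771766, rheMac2) in a 6.53 kb cluster with miR-424, miR-542 and miR-450, and is known to restrain cyclin D1 and other cell cycle genes. The other strand of its precursor, miR-503-3p, had a log2 fold change of 0.54 (SE 0.48). The 9 other tested arms of the cluster, looked up after the value of miR-503-5p was seen, lay between -1.55 and -0.03, and the abundant miR-424-5p had a value of -0.84 (SE 0.42). The gene mir-503 in the small RNA table had a log2 fold change of 1.81 (SE 0.32) and did not pass (adjusted p = 0.139, edgeR quasi-likelihood test). It passed in 3 of 20 alternatives, namely no filter, DESeq2 and the edgeR exact test (adjusted p from 0.00336 to 0.766 over all).

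The call of miR-503-5p was lost on all 6 libraries with limma voom (adjusted p = 0.0891), without robust estimation (0.0707), with age as a covariate (0.113) and with pairs by age (0.317), the last 3 by the edgeR quasi-likelihood test. It was lost without single libraries too: its adjusted p by the edgeR quasi-likelihood test was 0.308 without vehicle 7, 0.122 without vehicle 11, 0.297 without gonadotropin 8 and 0.125 without gonadotropin 12. Over 19 alternatives its adjusted p ran from 0.000109 to 0.317 and its log2 fold change from 1.51 to 2.12. It was called in 11. Among these 11 was the main fit read at a looser threshold of 0.10, which only repeats the main call.

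**Figure D1:**
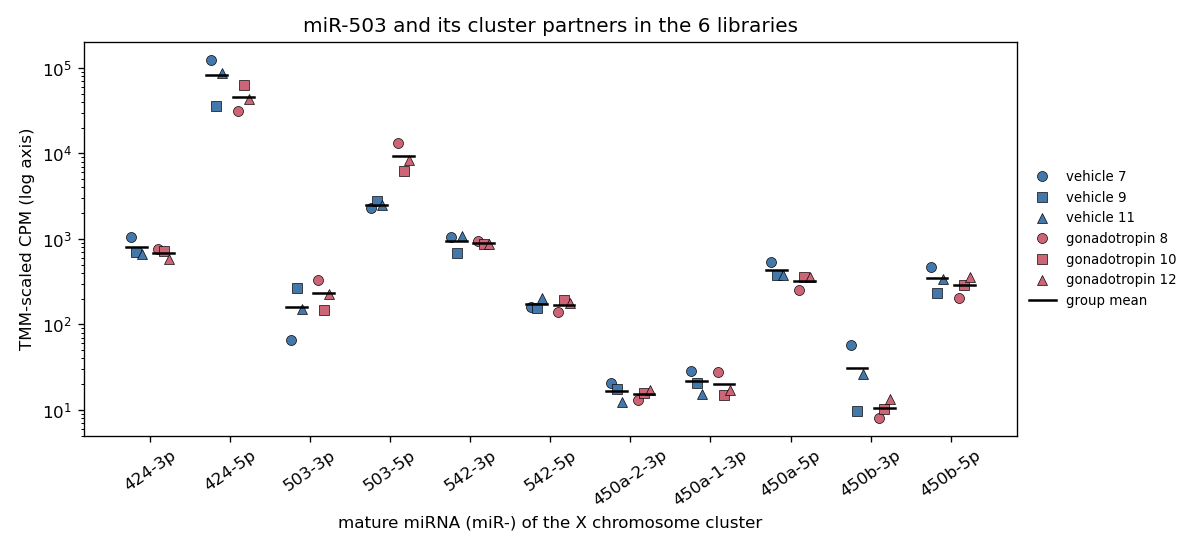
TMM-scaled CPM (log axis) of the miRNA arms of the miR-424 and miR-503 cluster in each library, with vehicle in blue, gonadotropin in red and group means as bars. miR-503-5p sat at 2287 to 2805 CPM in the vehicle libraries and at 6173 to 13114 CPM in the gonadotropin libraries, with no overlap.

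No other mature miRNA passed (edgeR quasi-likelihood test, 433 tested), and 26 had an unadjusted p under 0.05, 16 higher and 10 lower, where 21.65 are expected by chance. The groups did not overlap in 49 miRNAs (11.3%, chance 10%). The 16 with a higher value and an unadjusted p under 0.05 included miR-671-5p (1.18, SE 0.36), miR-484 (0.99, SE 0.34), miR-147b (0.98, SE 0.35) and miR-675-5p (1.20, SE 0.42), the last cut from the imprinted H19 transcript. miR-1260b had a value of 0.82 and miR-188-5p of 0.90. The 10 with a lower value included miR-582-5p (-1.04, SE 0.38), miR-450b-3p (-1.55, SE 0.57), miR-365-3p (-1.57, SE 0.61), miR-193a-3p (-1.06), miR-181c-5p (-0.69) and miR-302b (-1.08, SE 0.46), a miRNA of pluripotent cells. They also included miR-190a-5p (-1.71, SE 0.67), at 382 ± 394 CPM in vehicle, and miR-190a-3p (-1.36, SE 0.57). Vehicle 7 carried much of several of these values: without it the log2 fold change was -0.76 for miR-450b-3p, -0.48 for miR-365-3p, -0.52 for miR-193a-3p, -0.65 for miR-302b, -0.43 for miR-190a-5p and -0.40 for miR-190a-3p. miR-190a-5p (adjusted p = 0.0467) and miR-431 (adjusted p = 0.0254) passed the edgeR quasi-likelihood test without vehicle 9. These were the lowest adjusted p over their 19 alternatives, and the highest was 0.987 for each.

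The DLK1-DIO3 domain is an imprinted region of chromosome 7 that carries the DIO3 gene and a large cluster of miRNAs. Of 62 tested miRNAs of this list, 48 had higher and 14 lower values with gonadotropin, with a median log2 fold change of 0.34. miR-1185-3p was at 57.4 ± 2.82 CPM in vehicle and 150 ± 12.8 CPM in gonadotropin (1.38, SE 0.31, adjusted p = 0.132 by the edgeR quasi-likelihood test). It passed in 3 of 19 alternatives, namely library totals, DESeq2 and the edgeR exact test (adjusted p from 0.0105 to 0.484 over all). miR-665 (1.96, SE 0.52) and miR-431 (1.88, SE 0.53) had the next smallest p, with adjusted p of 0.331 and 0.42, and miR-665 passed with the edgeR exact test alone (0.037 to 0.987 over its alternatives). miR-370-5p (1.22, SE 0.55) and miR-370-3p (0.85, SE 0.43) lay in the same direction, at 0.76 to 1.89 and 0.66 to 1.27 without 1 library. By the edgeR quasi-likelihood test none of the members passed over all miRNAs and 1, miR-1185-3p, passed adjusted over the list alone. Of the members 7 had an unadjusted p under 0.05, all of them higher. The list ranked above the other miRNAs by camera (adjusted p = 1.2e-06), but not with an estimated correlation of 0.261 between members (adjusted p = 0.96 with an estimated correlation). fry, which asks only whether the members moved one way, gave an adjusted p of 0.988, and the range over the alternatives was 5.9e-15 to 0.988. The study, as recalled from its paper, pointed to this cluster from these same animals, so neither count is independent evidence of its direction.

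Among small RNA genes, 33 of the 36 tested genes of the DLK1-DIO3 list were higher, with a median of 0.51 (camera adjusted p = 2.1e-10, adjusted p = 0.645 with an estimated correlation, fry adjusted p = 0.415, range over alternatives 1.44e-20 to 0.645). None passed over all genes and 0 passed adjusted over the list alone. mir-665 (1.95, SE 0.57), mir-431 (1.76, SE 0.51) and mir-494 (0.98, SE 0.34) had the smallest p. The members span 163202837 to 163400596 of chromosome 7 (rheMac8). The SNORD112 to SNORD114 snoRNAs of the same domain had a median of -0.13 over 26 genes. The camera adjusted p was 0.994, and 0.996 with an estimated correlation of 0.78 between members. At the preset correlation the median was -0.59 without vehicle 7 (adjusted p = 0.000613), 0.34 without vehicle 9 (0.0244) and 0.19 without gonadotropin 12 (0.0208). Single libraries thus set its direction by camera (range over alternatives 0.000613 to 0.999). The members varied largely together, so adjusted p-values at the preset correlation are likely too small here. miR-1247-5p, encoded beside DIO3 (chromosome 7, 164844829 to 164844886, rheMac2), had a log2 fold change of -1.41 (SE 0.45, adjusted p = 0.604 by the edgeR quasi-likelihood test), from 13.6 ± 3.73 to 5.17 ± 1.35 CPM. In the miRNA table the list median was 0.56 without vehicle 9, 0.54 without gonadotropin 12 and 0.22 without gonadotropin 10. Vehicle 7 had the lowest mean log2 CPM of the list, relative to the miRNAs outside it, at -1.11. Gonadotropin 12 lay at -0.92 among the vehicle libraries (-0.90 and -0.61 in vehicle 11 and 9).

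**Figure D2:**
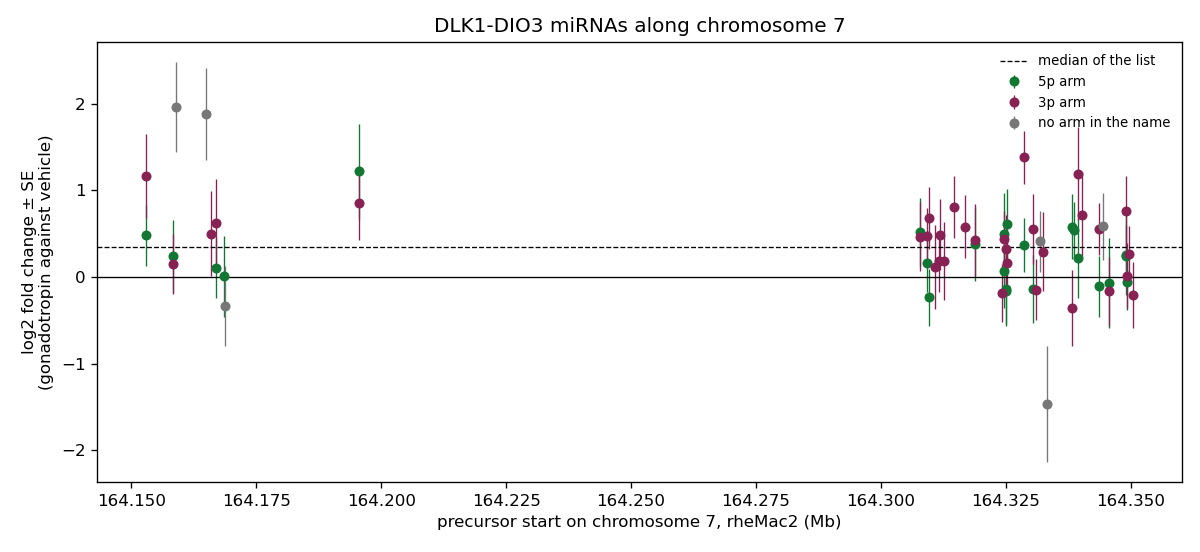
Log2 fold change (gonadotropin against vehicle, bars ± SE) of each tested DLK1-DIO3 miRNA at its precursor's place on chromosome 7 (rheMac2, Mb), coloured by arm, with the list median of 0.34 as a dashed line. Of the 62 values 48 lie above 0, with miR-665 (1.96) and miR-431 (1.88) the highest.

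The list of miRNAs reported to target deiodinases or thyroid hormone receptors had 7 members higher and 11 lower in the miRNA table (median -0.18, camera adjusted p = 0.934; 0.06 with library totals and 0.02 without vehicle 9) and a median of -0.01 in the small RNA table (0.851; 0.09 with library totals and 0.04 with upper-quartile scaling). Its members with an unadjusted p under 0.05 by the edgeR quasi-likelihood test were miR-1247-5p (-1.41, SE 0.45) and miR-221-3p (0.77, SE 0.35), in opposite directions. In the same list miR-383 had a value of -0.71 (SE 0.44), miR-214-5p of 0.44 (SE 0.32) and miR-214-3p of 0.08 (SE 0.35), the last turning to -0.05 with upper-quartile scaling. Without 1 library miR-383 ran from -0.94 to -0.30 and miR-214-5p from 0.29 to 0.75. The list of miRNAs responsive to gonadotropin or cAMP in gonadal cells had 9 members higher and 8 lower (median 0.04, camera adjusted p = 0.934; -0.05 with upper-quartile scaling). Its median in the small RNA table was -0.03 (0.923; 0.07 with library totals and 0.02 with upper-quartile scaling). miR-21-5p, abundant in testis, had a value of 0.58 (SE 0.29) and miR-21-3p of 0.98 (SE 0.59). Without 1 library they ran from 0.34 to 0.69 and from 0.55 to 1.81. miR-132-5p was at 0.15, miR-132-3p at -0.14 and miR-212-3p at 0.04; miR-132-3p turned to 0.12 with library totals and miR-212-3p to -0.03 with upper-quartile scaling. None of these passed the edgeR quasi-likelihood test, and 0 members of either list passed adjusted over the list alone.

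The let-7 family, which promotes differentiation and is opposed by LIN28, had 13 of 16 members lower in the miRNA table (median -0.24, camera adjusted p = 0.303), a median that turned to 0.02 with library totals. let-7b-5p was at 5378 ± 734 CPM in vehicle and 3319 ± 712 CPM in gonadotropin (-0.70, SE 0.30). let-7a-5p (-0.66, SE 0.33) and let-7f-5p (-0.75, SE 0.38) were among the 5 most abundant miRNAs, with miR-424-5p, miR-26a-5p (-0.19, SE 0.30) and miR-125b-5p (-0.14, SE 0.41); the last 2 turned to 0.04 and 0.08 with library totals. Without vehicle 7 the value was -0.36 for let-7a-5p, -0.32 for let-7f-5p and -0.42 for miR-424-5p. Among small RNA genes, 10 of 12 let-7 genes were lower (median -0.49, camera adjusted p = 0.0367; adjusted p = 0.959 with an estimated correlation, range over alternatives 0.000923 to 0.967), among them let-7b (-0.53) and let-7f-2 (-0.62; -0.09 without vehicle 7). The median was -0.11 without vehicle 7 (adjusted p = 0.721) and -0.24 without gonadotropin 8 (adjusted p = 0.642), both by camera. The let-7 offset from the other small RNA genes was 7.46 in vehicle 7 and 6.55 to 6.97 in the other libraries except gonadotropin 8, at 6.11.

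SNORD49B had lower counts in the gonadotropin than in the vehicle libraries, and whether the RNA itself was lower was not decided here. This C/D box snoRNA (ENSMMUG00000026295, named SNORD49 in the table; chromosome 16, 16240563 to 16240634, rheMac8) belongs to a class that guides 2'-O-methylation of ribosomal RNA. Its level was 144, 871 and 1177 CPM in vehicle 7, 9 and 11 and 6.82, 4.80 and 6.57 CPM in gonadotropin 8, 10 and 12, a log2 fold change of -6.91 (SE 0.85, adjusted p = 0.0215 by the edgeR quasi-likelihood test). Its neighbours SNORD49A (-0.03, SE 0.62) and SNORD65 (-0.31, SE 0.46), looked up afterwards, lie within 2 kb on the same chromosome. SNORD33 (ENSMMUG00000024003, chromosome 19, 44875708 to 44875792), also a C/D box snoRNA, was at 25.4 ± 12.9 CPM in vehicle and 4.04 ± 1.89 CPM in gonadotropin (-2.65, SE 0.54) and did not pass (adjusted p = 0.259, edgeR quasi-likelihood test). It passed in 3 of 19 alternatives, namely no filter, DESeq2 and the edgeR exact test (adjusted p from 0.00375 to 0.9996 over all).

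The call of SNORD49B was lost, by the edgeR quasi-likelihood test, without vehicle 11 (adjusted p = 0.112), gonadotropin 8 (0.407), gonadotropin 10 (0.199) or gonadotropin 12 (0.255), while its log2 fold change stayed between -7.38 and -6.36. On all 6 libraries it was lost with pairs by age (0.0761) and with limma voom (0.0523). Over 19 alternatives the adjusted p ran from 5.02e-26 to 0.407, with the call made in 13. Among these 13 was the main fit read at a looser threshold of 0.10, which only repeats the main call.

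**Figure D3:**
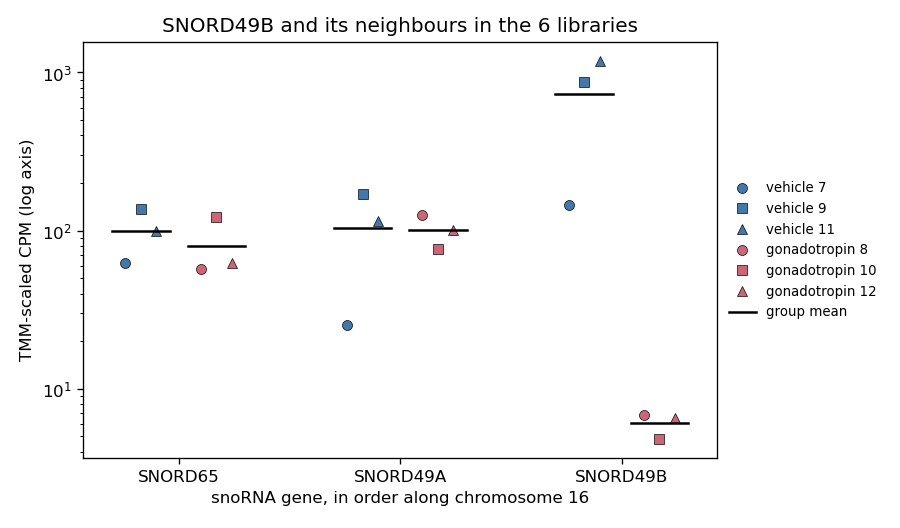
TMM-scaled CPM (log axis) of SNORD65, SNORD49A and SNORD49B in each library, with vehicle in blue, gonadotropin in red and group means as bars. SNORD49B is at 144 to 1177 CPM in the vehicle and 4.80 to 6.82 CPM in the gonadotropin libraries, and its neighbours overlap between groups.

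No other small RNA gene passed (edgeR quasi-likelihood test, 717 tested), 32 had an unadjusted p under 0.05, 18 higher and 14 lower, where 35.85 are expected, and the groups did not overlap in 59 (8.23%, chance 10%). MIR484 (1.12, SE 0.31) and mir-671 (1.14, SE 0.38) had higher values. U5 (-1.43, SE 0.48) and snoU83B (-1.43, SE 0.52) had lower values. U5 was at 16.1 CPM in vehicle 7 and its value was -0.89 without that library. A signal recognition particle copy (ENSMMUG00000048089) had a value of -3.42 (SE 1.29) that came from vehicle 9 alone, at 344 CPM, and was -0.05 without that library. The unnamed miRNA genes ENSMMUG00000046679 and ENSMMUG00000042824 (0.97 each, SE 0.33), which lie within the DLK1-DIO3 span, had near-identical counts and cannot be told apart.

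The brain-enriched, imprinted SNORD115 and SNORD116 snoRNAs had lower values in 30 of 30 tested copies (median -0.46, camera adjusted p = 2.1e-08; adjusted p = 0.645 with an estimated correlation, range over alternatives 7.43e-09 to 0.645). The copies with the smallest p were SNORD115 ENSMMUG00000039530 (-1.94, SE 0.52), from 6.74 ± 2.15 to 1.75 ± 0.919 CPM, and ENSMMUG00000040673 and ENSMMUG00000044991 (-1.24 each), whose counts were the same. Reads of such near-identical copies may be shared, so the 30 may not be separate measurements, and 0 passed adjusted over the list alone. Without vehicle 9 the median was -0.27 and without vehicle 7 it was -0.70. C/D box snoRNAs were taken as genes named SNORD, which leaves out snoU83B and includes the SNORD112 to SNORD116 copies. Of the 177 tested, 138 had lower and 39 higher values, with a median of -0.30. The camera adjusted p was 2.2e-05, and 0.959 with an estimated correlation (range over alternatives 8.03e-24 to 0.967). Of these genes 1, SNORD49B, passed, both over all genes and adjusted over the list alone. That median was 0.04 without vehicle 9 (adjusted p = 0.801), -0.14 without gonadotropin 12 (adjusted p = 0.091) and -0.50 without vehicle 7, by camera. snoRNAs made 1.75% of the counts in vehicle 7, 5.69% in vehicle 9 and 2.71 to 4.58% in the other libraries. H/ACA box snoRNAs had a median of 0.04 over 51 genes (camera adjusted p = 0.733) and small Cajal body RNAs of 0.02 over 12 (0.994).

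Mitochondrial tRNA and rRNA genes had lower values in 19 of 24 members (median -0.35, camera adjusted p = 1e-04; adjusted p = 0.792 with an estimated correlation, range over alternatives 9.88e-09 to 0.967). The tRNA genes ENSMMUG00000028679 (MT, 10396 to 10460; -0.97, SE 0.32) and ENSMMUG00000028687 (MT, 7463 to 7530; -1.24, SE 0.45) had the smallest p, and 0 passed adjusted over the list alone. A search made after the values were seen took genes at a median of at least 20 CPM in the other libraries that were, in 1 library, at least 8 times under that median and at least 4 times under the next lowest library. It found 7 of 20 such tRNA genes, all in gonadotropin 10, at 0.639 to 3.52 CPM, 9.44 to 2107 times under the median of the other libraries. The 13 others, which did not meet both conditions, were at 6.07 to 6492 CPM in that library. Most of them were lower there too, with a median log2 ratio of -1.08 to the median of the other libraries. By camera the list median was -0.16 without gonadotropin 10 (adjusted p = 0.367), -0.87 without gonadotropin 8 and -0.68 without gonadotropin 12. Mitochondrial tRNA made 1.03 ± 0.345% of the counts in vehicle and 1.14 ± 0.457% in gonadotropin libraries.

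**Figure D4:**
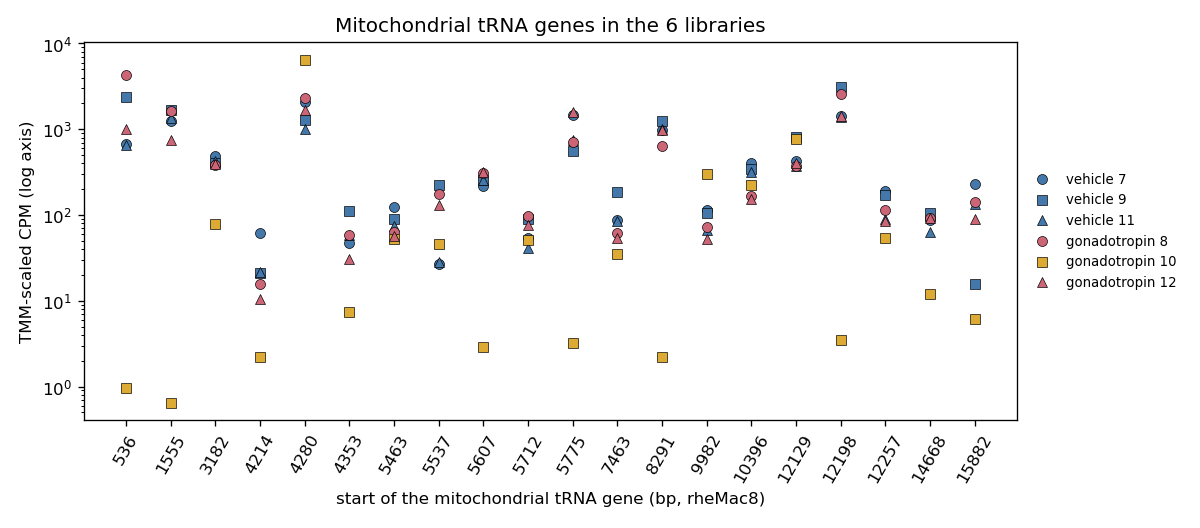
TMM-scaled CPM (log axis) of 20 mitochondrial tRNA genes in each library, by start on the mitochondrial genome (rheMac8), with gonadotropin 10 in yellow. Gonadotropin 10 is at 0.639 to 3.52 CPM for 7 genes at which the other libraries have medians of 21.1 to 1433 CPM.

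Markers of blood cells were higher in 11 of 11 genes of the small RNA table (median 0.30, camera adjusted p = 0.00363; adjusted p = 0.645 with an estimated correlation, range over alternatives 8.14e-05 to 0.645), with the smallest p for the myeloid mir-223 (0.91, SE 0.37) and for mir-342 (0.62, SE 0.37; 0.38 without vehicle 7). Among mature miRNAs, 9 of 12 were higher (median 0.17, camera adjusted p = 0.303), with miR-223 at 0.74 (SE 0.35) and miR-142-5p at 0.52 (SE 0.42). That median was 0.03 without gonadotropin 8 and 0.39 without vehicle 11, and miR-142-5p was at 0.15 without vehicle 7. In the small RNA table the median was 0.15 without vehicle 9 (camera adjusted p = 0.178) and 0.66 without vehicle 11. Y RNAs, noncoding partners of the Ro protein, were higher in 10 of 11 genes (median 0.30, camera adjusted p = 0.00369; adjusted p = 0.792 with an estimated correlation, range 6.3e-05 to 0.957), with the smallest p for ENSMMUG00000034543 (1.19, SE 0.39) and for ENSMMUG00000028452 (1.11, SE 0.78). The latter was at 2.18 CPM in vehicle 7 and at 23.6 to 62.0 CPM in the others, and its value was 0.62 without vehicle 7 and 0.51 without gonadotropin 10. The Y RNA median was 0.21 without vehicle 7 (camera adjusted p = 0.146), 0.92 without vehicle 9 and 0.46 without gonadotropin 10. No blood or Y RNA gene passed adjusted over the list alone (0 in each, edgeR quasi-likelihood test).

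miRNA genes as a class had a median of 0.06 over 372 genes (camera adjusted p = 0.000572; adjusted p = 0.847 with an estimated correlation, range over alternatives 2.58e-16 to 0.967), with 219 higher, 153 lower and 0 called. By camera it was -0.08 without vehicle 9 (adjusted p = 0.178), 0.02 without gonadotropin 10 (0.235) and -0.000214 without gonadotropin 12 (0.289), against 0.17 without vehicle 7 and 0.15 without gonadotropin 8. miRNAs made 94.3 ± 2.53% of the counts in vehicle and 94.3 ± 1.45% in gonadotropin libraries. Shares of RNA classes could not pass an exact two-sided permutation test, whose smallest p is 0.1; it was reached by the sRNA class alone, which had only 1 to 7 counts per library over its 4 genes.

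Markers of other cells gave no camera call in the miRNA table, where the adjusted p was 0.934 for each: the median was 0.13 for endothelium, -0.14 for muscle, 0.14 for duct epithelium and 0.12 for neural miRNAs. In the small RNA table these were 0.35 (adjusted p = 0.105), -0.01 (0.985), 0.21 (0.733) and 0.21 (0.318), and liver had 0.13 (0.733). Germ cell lists gave none either. In the miRNA table pluripotency and primordial germ cell miRNAs had a median of -0.20, undifferentiated spermatogonia -0.13 and the meiotic miR-34 and miR-449 families 0.04, with medians of -0.12, 0.07 and 0.13 in the small RNA table (camera adjusted p = 0.733, 0.702 and 0.449). The miR-17 to miR-92 clusters (-0.04), the X-linked miR-506 to miR-514 cluster (-0.06), the primate C19MC cluster (-0.07), Sertoli and gonadal somatic (-0.35), fibroblast (-0.01) and hypoxia miRNAs (-0.08) had a camera adjusted p of 0.934 each in the miRNA table. Except for endothelium in the small RNA table, which kept its sign, these medians did not hold their direction. Over all lists 16 of 18 medians of the miRNA table and 22 of 29 of the small RNA table turned sign in at least 1 alternative. With library totals, which moved the median of all miRNAs to 0.19, they turned to 0.11 for muscle, 0.07 for pluripotency, 0.13 for undifferentiated spermatogonia, 0.20 for miR-17 to miR-92, 0.19 for the X-linked cluster, 0.16 for C19MC, 0.24 for fibroblast and 0.22 for hypoxia. The meiotic (-0.04) and neural (-0.003) medians turned with upper-quartile scaling. Without vehicle 7 the medians were 0.01 for pluripotency, 0.24 for undifferentiated spermatogonia, 0.47 for the meiotic families and 0.38 for hypoxia. In the small RNA table the medians were 0.01 for miR-17 to miR-92, 0.15 for the X-linked cluster and 0.05 for C19MC (camera adjusted p = 0.766, 0.733 and 0.766). There they were 0.04 for Sertoli and gonadal somatic and 0.11 for fibroblast miRNAs (camera adjusted p = 0.994 and 0.844). The hypoxia list was too small to test in that table. Spliceosomal RNAs (0.05, 0.733), 7SK and vault RNAs (0.67, 0.15) and ribosomal RNAs (0.32, 0.702) were not called either. Of these small RNA lists, endothelium, pluripotency, undifferentiated spermatogonia and the meiotic families were called in 1 alternative each, and miR-17 to miR-92 and 7SK and vault RNAs in 2 each. The median, the mean and the direction of camera did not all have the same sign for the X-linked cluster, undifferentiated spermatogonia and neural lists of the miRNA table, nor for the deiodinase, gonadotropin, fibroblast, Sertoli, spliceosomal, Cajal body and SNORD112 to SNORD114 lists of the small RNA table. miR-210-3p, the miRNA most tied to hypoxia, was at -0.48 (SE 0.36), and at -0.82 to -0.18 without 1 library.

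The log2 fold changes of 259 miRNAs named in both tables had r = 0.964 (95% interval 0.954 to 0.972) and rho = 0.966 across miRNAs, which are not replicates, and 218 (84.2%) had the same sign. Both tables come from the same libraries, so they are not independent. The authors' deposited table lists 3 mature miRNAs under an adjusted p of 0.05: miR-503-5p (1.94, adjusted p = 0.000497), miR-1185-3p (1.45, 0.0369) and miR-665 (2.01, 0.0369), all by the edgeR exact test. The authors' deposited table of small RNA genes lists SNORD49B (-6.92, adjusted p = 1.49e-12) and SNORD33 (-2.66, 0.0109) by the same test. Of each set the edgeR quasi-likelihood test called 1, miR-503-5p and SNORD49B.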

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

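The values below are gonadotropin against vehicle by the edgeR quasi-likelihood test or camera unless another tool is named; keeping identical or near-identical copies once and taking the DLK1-DIO3 genes by position were chosen after seeing the data. Calls among mature miRNAs, 1 in the report, were 2 with library totals, 2 with DESeq2, 3 with the edgeR exact test, and 0 with limma voom, without robust estimation, with age pairs and with age as a covariate. Without 1 library they were 0 to 4: 0 without vehicle 7, vehicle 11, gonadotropin 8 or gonadotropin 12, 1 without gonadotropin 10 and 4 without vehicle 9. Calls among small RNA genes, 1 in the report, were 3 without a filter, 3 with DESeq2, 3 with the exact test, and 0 with voom, with age pairs and with miRNA genes alone. Without 1 library they were 0 to 1, with 0 without vehicle 11, gonadotropin 8, gonadotropin 10 or gonadotropin 12. With fewer libraries the residual degrees of freedom fall; otherwise the cause was not tested. The fits with 0 calls had 22, 29, 16 and 21 miRNAs (voom, no robust estimation, age pairs, age covariate) and 32, 19 and 22 small RNA genes (voom, age pairs, miRNA genes alone) at an unadjusted p under 0.05.

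Called lists went from 1 to 0 in the miRNA table with an estimated correlation and with fry, one-way or mixed. In the small RNA table they went from 8 to 0 with both, to 3 without a filter, and to 3 with miRNA genes alone, where the small RNA classes drop out; without 1 library they were 6 to 9. The DLK1-DIO3 median is 0.34 and 0.51 in the 2 tables with either test, and its call was lost there (adjusted p = 0.96 and 0.645 with an estimated correlation, 0.988 and 0.415 with fry). It ran from 0.22 to 0.56 and from 0.36 to 0.67 without 1 library and was called in every such fit. Over all alternatives the adjusted p ran to 0.988 and 0.645. With all libraries kept, over scaling and the other settings, the median ran from 0.26 to 0.61 and from 0.38 to 0.63. By position it was 0.55 over 40 genes (adjusted p = 1.1e-12 at the preset correlation and 0.645 with an estimated correlation). The correlation between tables was 0.885 over 334 names without a filter, where scarce miRNAs enter, and 0.965 with library totals.

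In at least 1 alternative, 16 of 18 list medians turned sign in the miRNA table and 22 of 29 in the small RNA table. Of these turned medians 0 and 2 were called at the preset correlation, the 2 both of SNORD112 to SNORD114. That list had an estimated correlation of 0.78 between members. Among values that turned with all libraries, none of them past a threshold in the alternative, were miR-214-3p (-0.053) and miR-212-3p (-0.033) with upper-quartile scaling; the let-7 median of the miRNA table (0.019), miR-26a-5p (0.041), miR-132-3p (0.12) and miR-125b-5p (0.078) with library totals; miR-125b-5p with voom (0.041) and with age pairs (0.042); and the miRNA class median with DESeq2 (-0.0031). Library totals also moved the median of all miRNAs, to 0.19; for the others the cause was not tested. Without 1 library the range was -0.40 to 0.046 for miR-132-3p, -0.11 to 0.38 for miR-132-5p, -0.17 to 0.55 for miR-214-3p, -0.093 to 0.53 for miR-212-3p, -0.33 to 0.027 for miR-26a-5p, -0.49 to 0.37 for miR-125b-5p, -0.50 to 0.042 for the C/D box median and -0.084 to 0.17 for the miRNA class median. Of the other values of single genes and lists, 1301 kept direction and side of the threshold, 48 lost a call and 12 gained one. The miRNA share differed by 0.05 points, by -0.13 without the most abundant gene and by -1.16 to 1.36 without 1 library. The authors' tables list 4 miRNAs and 2 small RNA genes under an adjusted p of 0.10.

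Replicate numbers are not shared between groups, so they gave no pairs. Pairs by age (14 with 14, 15 with 15, 24 with 22 months) gave 0 calls in both tables; the deviations of paired libraries correlated at -0.13, -0.04 and 0.12 in the miRNA table and -0.22, 0.01 and -0.13 in the small RNA table, so age did not pair the libraries. No miRNA name was duplicated, so keeping or summing several rows of a name would change nothing. Identical names or near copies kept once gave 1 call in each table, with 1 called list in the miRNA table and 7 in the small RNA table. The simulated recovery of 2-fold changes, 31% and 12%, limits what 3 libraries per group can show. It is likely lower still where few genes change, since 100 genes were changed at each fold in the simulation.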

Other observations

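All tests of explanations for SNORD49B, miR-503-5p and the DLK1-DIO3 list were chosen only after the result was seen; the splits of the libraries were planned. The search over 472 small RNA genes for a level in a single library at least 8 times under the median of the others and at least 4 times under the next lowest found 11 losses. They were 7 of 20 mitochondrial tRNAs, all in gonadotropin 10, 3 of 137 snoRNAs, 1 Y RNA in vehicle 7 and 0 of 284 miRNAs. The 3 snoRNAs were copies of SNORD113 in the DLK1-DIO3 domain: ENSMMUG00000048064 was at 1.55 CPM in gonadotropin 12 against a median of 327, ENSMMUG00000026081 at 3.61 CPM in gonadotropin 8 against 90.8, and ENSMMUG00000026549 at 2.61 CPM in vehicle 7 against 37.2.

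SNORD49B was lower in all 3 gonadotropin animals at once, with a log2 fold change of -6.91. A lower level of the RNA that carries the neighbouring snoRNAs is argued against by those neighbours, of which the lower had a value of -0.31 (SE 0.46). A lower yield of C/D box snoRNAs is argued against by the other 176 genes named SNORD. Their median was -0.29, with 95% of values between -0.98 and 0.33. A difference between the DNA of the animals and the reference genome that keeps reads from being counted stays a candidate explanation that these tables do not decide. Of the 11 losses in single libraries 7 were mitochondrial tRNAs of gonadotropin 10. They lie on the mitochondrial genome of 1 animal, so they may not be separate events. The others were 1 each in gonadotropin 8 and 12 and 2 in vehicle 7, so neither group stood out among them. SNORD49B was 120 times lower by its log2 fold change. The mitochondrial losses were 9.44 to 2107 times. The loss in gonadotropin 12 was 211 times, that in gonadotropin 8 was 25.2 times, and those in vehicle 7 were 14.2 and 11.05 times. Losses as large were thus seen only among mitochondrial tRNAs of gonadotropin 10 and in the SNORD113 copy of gonadotropin 12. The tRNAs lie on the mitochondrial genome, and reads of SNORD113 copies may be shared. These sizes therefore do not show how large such a loss of SNORD49B could be. An effect of the hormones on SNORD49B stays open and untested.

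miR-503-5p was higher by 1.87 (log2, 1.19 to 2.55 at 2 approximate SE either side). A rise of all mature miRNAs of the cluster by as much is argued against by 9 other arms, with a median of -0.22 (SD 0.50). Those 9 leave out miR-503-3p of the same precursor, at 0.54 (SE 0.48). Whether the cluster transcript changed cannot be told here, since levels of mature miRNAs also depend on processing and decay. A constant share of miR-424-5p reads counted as miR-503-5p would have lowered the latter, since miR-424-5p had a value of -0.84; a share that differs between the groups was not tested. An effect of the hormones on miR-503 was not tested apart from the groups. Donor differences between the 2 groups of 3 animals stay open as well.

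The DLK1-DIO3 miRNAs were higher by a median of 0.34 in the miRNA table and 0.51 in the small RNA table. Vehicle 7 as the only cause is argued against by a median of 0.34 without it. A change of all RNAs of the domain could not be decided: its snoRNAs, relative to other C/D box snoRNAs, differed by 0.22 (SE 0.49), and its miRNAs, relative to other miRNAs, by 0.53 (SE 0.31), a difference of -0.31 (SE 0.25, exact permutation p = 0.3). The estimated correlation of 0.261 between members, with which the call is lost (adjusted p = 0.96), leaves open that a few animals differ in this domain for reasons other than the hormones.

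With 3 libraries against 3 there are 10 splits, so a share under 0.05 cannot be reached. The real split gave 1 called miRNA and 1 called small RNA gene, and the highest other split 0 in each table; 1 split of 10 had as many in each. Called lists were 1 in the miRNA table (highest other 2, 7 splits with as many) and 8 in the small RNA table (highest other 11, 4 splits with as many). The DLK1-DIO3 median was 0.34 in the miRNA table (highest other 0.51, 3 splits as large) and 0.51 in the small RNA table (highest other 0.49, 1 split as large).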
